A study of Homo sapiens with 40 samples.

How the data were processed

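RNA was measured in cultured human lung fibroblasts, 5 control lines and 5 IPF lines, each grown for 18 h on decellularized control and IPF lung matrix. Per the labels, cycloheximide fixed ribosomes on RNA, a sucrose gradient separated the polysome-associated RNA, and both fractions were extracted with Tri Reagent, amplified and labelled with biotin. Each of the 40 libraries was hybridized to an Illumina beadchip, with 5 libraries in each of 8 groups. The labels name the line and 1 of 6 batches for each culture. Of these batches, 4 hold a control and an IPF line, 1 holds a control line only and 1 an IPF line only.

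The deposited raw values are intensities, per the file headers, with no normalization between arrays and apparently without background subtraction. A detection p-value stands beside each intensity per the file headers. The deposited table of processed values is on the log2 scale, and its columns have medians of 6.92 to 6.94 and nearly equal quartiles, so the authors normalized between arrays. Each of its columns ranks probes exactly as the raw column of the same library does (rank correlation 1), and its highest correlation with another library was 0.891. The authors' method of normalization and the tools behind it are not given in the sources used here. No 2 raw columns were identical, and the highest correlation between libraries was 0.988.

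Raw intensities were corrected for background by normexp with the detection p-values (offset 16), quantile-normalized over all 40 arrays and taken to log2 in limma 3.58.1 under R 4.3.3, with statmod 1.5.0 and the package data.table (version 1.17.8). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Of 47323 probes, 30113 have 1 gene symbol, 8 have several and 17202 have none. A probe was tested if its detection p was under 0.05 on at least 5 of 40 arrays, which left 22365 probes. The probe with 1 symbol and the highest mean stood for its gene, which left 12131 genes. Genes of the Y chromosome and XIST were left out (144 probes), and 39 gene identifiers were not in the reference of gene names. Among named results, 135 had at least 2 detected probes. Of the 25 of them past the threshold, 2 had another probe of opposite sign, both in polysome against total RNA (COL1A2, second probe −0.15, and the phosphofructokinase gene PFKL, −0.02).

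The matrix effect is IPF minus control matrix within a line, with the line as a fixed block and the effects of control and IPF fibroblasts averaged. It was fitted in total RNA, in polysome RNA and in the difference of their log2 values per culture. The effect within each origin and the interaction come from the same fits. The difference between origins is IPF minus control fibroblasts on 10 line means, with the batch as a random block (consensus correlation 0.356 in total RNA, 0.419 in polysome RNA and 0.295 in their difference). Polysome against total RNA was tested on line means of the difference. All fits used limma with a trended variance, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. The pairing by line rests on the line named in the labels. As a check, the deviations of the 2 cultures of a line from their group means were correlated across genes. In each fraction 9 of 10 pairs had r over 0.1, with medians of 0.38 in total RNA and 0.42 in polysome RNA. The culture on control matrix correlated best with the IPF matrix culture of its own line, among lines of its origin, in only part of the pairs. These were 6 of 10 in total RNA and 7 of 10 in polysome RNA.

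Gene lists, 28 of pathways and complexes and 7 of cell type markers, were fixed before the data were examined. They were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 35 lists of a comparison. For the difference between origins, camera was run on line means without the batch block, which it does not take. The list medians given beside those tests come from the fit with the batch block. Members were also counted past the threshold over all genes and adjusted over the list alone. Exact two-sided tests on list means per line, added after the data were seen, flip the sign of each line's value (10 lines) or regroup the lines (5 against 5). Lists of lysosomal, surface receptor and cytosolic enzyme messages were also chosen after the data were seen.

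Named genes were chosen by a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls past the threshold that point the same way in at least 9 of 10 lines, or, between origins, with groups of lines that do not overlap. Where fewer than 3 pass in a direction, it takes the 3 with the smallest p as values only. It adds the 4 members with the smallest p of each list that passed, and always a short set of genes that includes COL1A1, COL1A2, COL3A1, FN1, ACTA2, CCN2, TGFB1 and POSTN. TGFB1 did not pass detection. Loci without a gene name were passed over. The exceptions are CCL7 within control fibroblasts, genes named as single lines that stand apart, and the members of lists chosen after the data were seen.

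Depth per array is given by the detected probes, whose group means ± SD (n = 5) were 16641.4 ± 424 in total RNA of control fibroblasts on control matrix and 15217.4 ± 1585.21 on IPF matrix. They were 16134.6 ± 452 and 15318.2 ± 1386.3 in total RNA of IPF fibroblasts. In polysome RNA they were 15756.2 ± 1214.41 and 16117.6 ± 1669.4 for control and 15658.8 ± 1680.66 and 15467 ± 1006.13 for IPF fibroblasts. The median intensity per array was 99.3 to 154.5 and the 95th percentile 618 to 1277, so a gene near background shows a compressed effect. Precision is set by 10 lines for matrix effects and 5 against 5 for the origin of the cells. The sample details used here name no donor lung for the matrix. Errors and p-values of matrix effects therefore measure spread between fibroblast lines. How many lungs supplied the matrix, and whether lines shared them, is unknown here.

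Each fit was tested on simulated data of 12131 genes in which 200 had changed by 0.5, 1 or 2 log2 units. For the matrix effect it recovered 31.3%, 82.1% and 100% of the changed genes in total RNA (4.05% of calls false), 19.4%, 79.1% and 100% in polysome RNA (6.38%) and 28.4%, 71.6% and 100% in their difference (6.99%). Within control fibroblasts it recovered 13.4%, 58.2% and 97.0% in total RNA (5.88%), 5.97%, 49.3% and 95.5% in polysome RNA (3.85%) and 2.99%, 43.3% and 97.0% in the difference (3.06%). For the interaction it recovered 0%, 23.9% and 84.8% (1.37%), then 1.49%, 16.4% and 72.7% (1.64%), and 0%, 10.4% and 68.2% (5.45%) in the same order. For the origin of the cells it recovered 10.4%, 53.7% and 95.5% (0.935%), then 4.48%, 38.8% and 97.0% (7%), and 2.99%, 38.8% and 90.9% (4.35%). For polysome against total RNA it recovered 50.7%, 95.5% and 100% (4.09%), and the regression of polysome on total RNA recovered 8.96%, 70.1% and 97.0% of matrix effects (6.4%). A matrix effect or a difference between origins of 0.5 log2 units in a single gene would therefore mostly be missed. In simulated lists of 30 genes shifted by 0.4, all 3 list tests found 100% of 20 shifted lists and called 1%, 0% and 2% of 100 unchanged ones with the preset correlation, the estimated correlation and the exact test. The simulated genes vary independently, so these rates hold for uncorrelated lists only.

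Alternatives changed 1 choice at a time. They were no background correction, normalization within each fraction, the authors' values, no detection filter, detection on all 40 arrays, all probes, array quality weights, no block for the line, separate fits of the origins, a regression of polysome on total RNA, other uses of the batch, 1 matrix only, and each line left out in turn. Added after the data were seen were the runs without the 2 libraries of control line 1 that lie with the other fraction, without batch 2, without control line 1 and batch 2, with a covariate for sets of batches, and the exact test on list means. Without those 2 libraries control line 1 has no pair of cultures in any measure. Matrix effects in that run therefore rest on the same lines as without control line 1. Probes without a gene name were tested only in the run with all probes.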

Results

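Human lung fibroblasts were profiled after 18 h on decellularized lung matrix, the protein scaffold left when the cells of a lung are washed out. The fibroblasts came from 5 control lines and 5 lines from idiopathic pulmonary fibrosis (IPF), and each of the 10 lines was grown both on control matrix and on IPF matrix. Total RNA and polysome-associated RNA, a ribosome-loaded fraction that the sample titles call heavy, were measured separately in each culture on Illumina expression beadchips. This gave 40 arrays in 8 groups of 5, 1 array per line, matrix and fraction. Per array, 12707 to 18069 probes were detected over background (median 16143.5), and 12131 genes were tested. Arrays hold no counts, so their number limits the precision. The median SE of a matrix effect was 0.14 log2 units in total RNA and 0.16 in polysome RNA (10 lines), and that of a difference between cell types was 0.15 and 0.19.

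In total RNA, lines within an origin took 51.8 ± 4.64% of the spread of a gene's values (jackknife SE, n = 10 lines), the matrix 5.82 ± 0.97% and the origin of the cells 5.10 ± 2.50%. In polysome RNA these shares were 55.3 ± 6.18%, 5.77 ± 1.20% and 3.96 ± 1.95%. A spread divided equally over the degrees of freedom would give lines 42.1% and the matrix or the origin 5.26%. The difference between the shares of matrix and origin, 0.73 ± 2.50 percentage points in total RNA and 1.81 ± 2.87 in polysome RNA, was smaller than its error. Over all arrays the mean log2 intensity was 14.12 for the filament gene VIM and 12.9 for the collagen gene COL1A2. Markers of other cell types spanned a wide range, from 5.06 for EPCAM to 8.01 for MUC1 among epithelial genes and from 5.17 for VWF to 6.46 for CLEC14A among endothelial genes. The macrophage gene CD68, also a lysosomal protein, had 11.03 and the hemoglobin gene HBB 5.20. Probes differ in how they hybridize, so these intensities do not rank the genes by abundance.

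Polysome RNA was first set against total RNA, a comparison of which messages were enriched in the heavy fraction. MMP14, a membrane-bound collagenase, was higher by 2.78 ± 0.32 log2 units (SE, n = 10 lines, adjusted p = 1.11e-05; 9 of 10 lines). LTBP3, which binds latent TGF-beta, was higher by 2.13 ± 0.22, the collagen hydroxylase P3H3 by 2.06 ± 0.23, the proteoglycan GPC1 by 1.98 ± 0.18 and the lysosomal glucosidase GAA by 2.15 ± 0.21. TMEM132A (2.27 ± 0.19), the chondroitin synthesis gene CHPF (2.12 ± 0.23) and ISLR (2.08 ± 0.21) complete the 8 largest rises. The 8 largest falls include SNORD13 (−2.63 ± 0.34) and RNU1-3 (−2.20 ± 0.19), a small nucleolar and a spliceosomal RNA, which ribosomes do not translate. The ribosomal protein genes RPL26 (−2.50 ± 0.28) and RPL21 (−2.41 ± 0.24), the snoRNA host SNHG5 (−2.28 ± 0.26), GNG10 (−2.54 ± 0.27), PPDPF (−2.26 ± 0.29) and MZT1 (−2.24 ± 0.23) fell as well.

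Of 12131 genes, 3337 were higher and 2744 lower on polysomes by limma at an adjusted p under 0.05 (lowest 2.78e-06). Without 2 libraries of control line 1 that lay with the opposite fraction, 6580 genes passed, 3572 up and 3008 down. Among the genes followed throughout, COL1A2 was higher on polysomes (0.95 ± 0.18, adjusted p = 5.08e-04; a second probe had −0.15), as was ACTA2, the smooth muscle actin of myofibroblasts (0.57 ± 0.15, adjusted p = 0.00491). COL3A1 was lower (−0.53 ± 0.14, adjusted p = 0.00654), with −0.98 on control matrix alone and −0.09 on IPF matrix alone, where it did not pass (adjusted p = 0.753). COL1A1 (−0.06 ± 0.14), FN1 (0.26 ± 0.12), POSTN (−0.21 ± 0.13) and CCN2 (0.26 ± 0.12) did not pass.

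Among gene lists fixed in advance, 13 of 35 passed in this comparison. Of 23 collagen processing and crosslinking enzymes, 19 rose and 2 fell, over all genes and adjusted over the list alone (median 1.05, adjusted p = 8.06e-06). Of 21 matrix proteases and inhibitors, 15 rose over all genes and 16 adjusted over the list alone (median 0.83, adjusted p = 7.92e-05). Glycolysis and hypoxia genes (21 of 30 up, median 0.46, adjusted p = 0.00477) were also higher on polysomes. So were integrins and focal adhesion genes (16 of 28 up, 4 down; median 0.44, adjusted p = 0.0153), cholesterol biosynthesis genes (10 of 19 up; median 0.34, adjusted p = 0.0221) and non-collagen matrix proteins (17 of 38 up, 5 down; median 0.25, adjusted p = 0.0474). Adjusted over the list alone, 22 glycolysis genes, 18 integrin and adhesion genes, 10 cholesterol genes and 17 matrix proteins rose. With an estimated correlation the adjusted p was 0.506 to 0.61 for these 6 lists.

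Cytosolic ribosomal protein messages were the most uniformly depleted group. They open with a pyrimidine tract that lets cells hold them off ribosomes, and whether it bears on this depletion was not tested. Of 69 measured, 63 fell over all genes and 64 adjusted over the list alone (median −0.84, adjusted p = 3.15e-19), and adjusted p = 0.506 with an estimated correlation. Non-coding RNAs fell in 25 of 35 cases (26 adjusted over the list alone; median −0.89, adjusted p = 4.54e-09). Messages with inhibitory upstream reading frames fell in 14 of 20 cases over all genes and adjusted over the list alone (median −0.58, adjusted p = 1.3e-04), although CEBPB was higher by 1.08. Translation factors fell in 26 of 46 cases and rose in 10 (median −0.35, adjusted p = 0.0037). Oxidative phosphorylation subunits fell in 33 of 67 and rose in 12 (median −0.25, adjusted p = 0.00489). Replication-dependent histones fell in 10 of 20 (median −0.24, adjusted p = 0.0217) and KRAB zinc finger genes in 22 of 89 (median −0.11, adjusted p = 0.0344; ZNF324 was higher by 1.5). Adjusted over the list alone, 26 translation factors, 33 respiratory subunits, 10 histones and 21 zinc finger genes fell. With an estimated correlation the adjusted p of these 6 lists was 0.506, or 0.61 for the oxidative phosphorylation subunits. Exact sign-flip tests on the mean of each list per line, chosen after the data were seen, passed for 31 of 35 lists. With detection required on all 40 arrays the median of histones turned to 0.06 without passing. In that run 8 lists and 3830 genes passed, and with all probes kept 9211 passed.

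**Figure D1:**
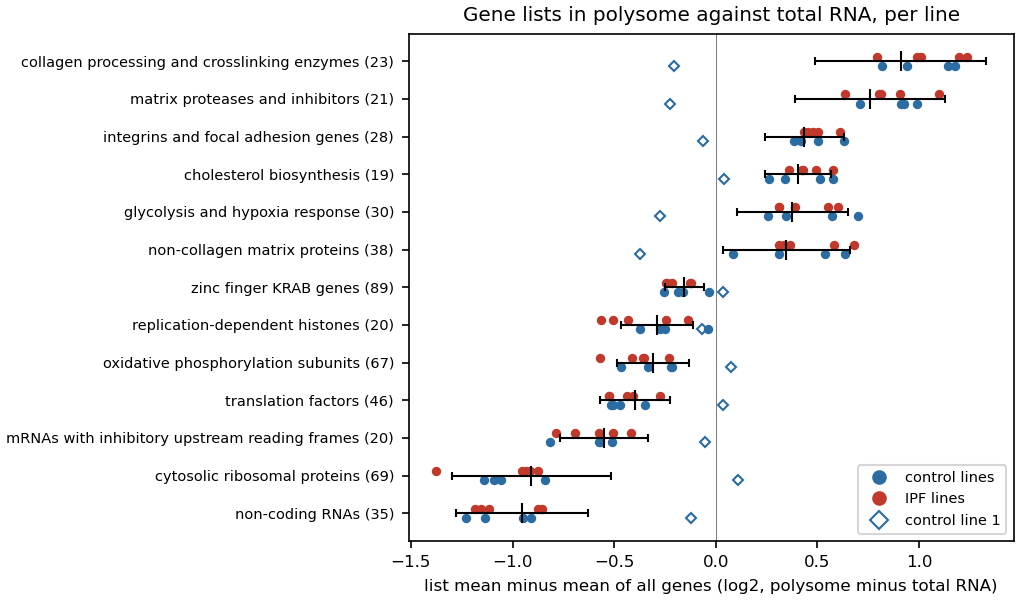
Each point is the mean of a gene list in 1 line, polysome minus total RNA in log2 units, for the 13 lists that passed, with the number of measured genes in parentheses and bars for mean and SD over 10 lines. Collagen processing enzymes lie highest, and cytosolic ribosomal proteins and non-coding RNAs lie lowest.

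A score built from the 200 genes most enriched and the 200 most depleted on polysomes in the other lines placed 2 libraries of control line 1 with the opposite fraction. The library labelled polysome RNA on control matrix scored −0.01, inside the range of total RNA in the other 9 lines (−0.38 to 0.09). The library labelled total RNA on IPF matrix scored 1.16, inside the range of polysome RNA (0.67 to 1.38). The other libraries of the line scored 1.04 for polysome RNA on IPF matrix and −0.01 for total RNA on control matrix. All 4 were kept under their labels.

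**Figure D2:**
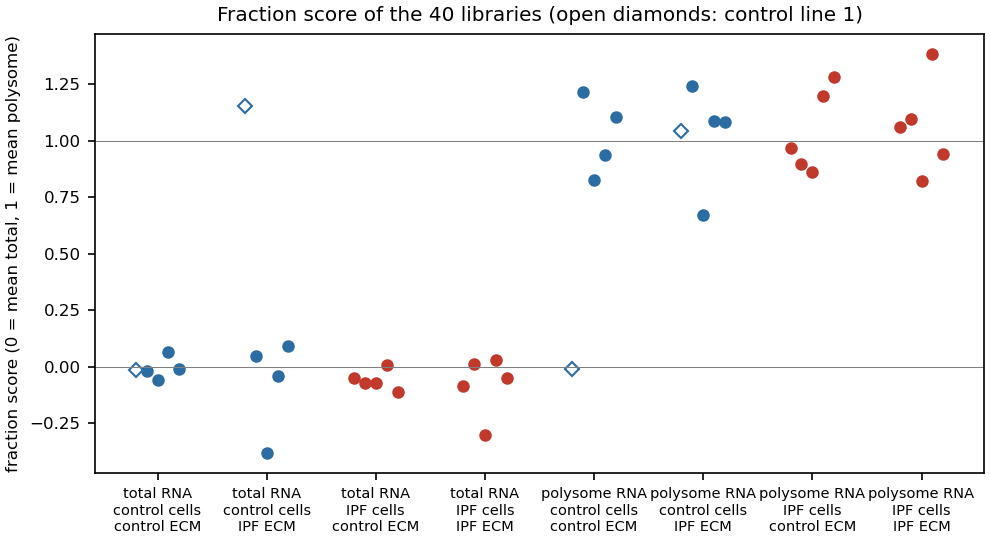
The vertical axis shows the fraction score for 40 libraries in the 8 groups on the horizontal axis. The score is the mean difference between polysome-enriched and polysome-depleted genes. It is scaled by the mean total RNA and mean polysome RNA scores of the other lines and so has no unit. Blue points are control fibroblasts, red points are IPF fibroblasts, and open diamonds are control line 1, whose libraries at −0.01 and 1.16 lie with the other fraction.

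The series asks, by its title, whether matrix from fibrotic lung changes translation in fibroblasts, and the matrix effect in polysome RNA addresses this. On IPF matrix, 6 genes rose in polysome RNA and none fell. The basement membrane genes COL7A1, the collagen of anchoring fibrils, and LAMB2, a laminin chain, rose by 1.24 ± 0.17 and 1.17 ± 0.16 log2 units (SE, n = 10 lines, adjusted p = 0.00949 for both; all 10 lines). LRP1, an endocytic receptor for proteases, rose by 1.31 ± 0.21 (adjusted p = 0.0426; 10 of 10 lines). SERPINE2, an inhibitor of serine proteases, rose by 1.31 ± 0.22 (adjusted p = 0.048; 10 of 10). FSTL3, a secreted activin antagonist, rose by 1.01 ± 0.17 (9 of 10) and ITPRIP, a modulator of the inositol trisphosphate receptor, by 0.89 ± 0.15 (10 of 10), both at an adjusted p = 0.0438. The folds ranged from 1.86 for ITPRIP to 2.48 for SERPINE2. The 3 lower genes with the smallest p were PPIA (−0.79 ± 0.17), FAM162B (−0.59 ± 0.13) and SRSF9 (−0.51 ± 0.11), lower in all 10 lines with adjusted p of 0.137, 0.168 and 0.168.

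Without the 2 libraries of control line 1, 13 genes passed in polysome RNA, 10 up and 3 down. The count of 6 became 0 to 13 when single lines were left out, 1 without the pairing by line, 2 without a detection filter, 3 with all probes and 220 with array quality weights. None of the 6 genes passed under every setting, and COL7A1 kept a value of 1.04 to 1.43 (adjusted p from 6.11e-05 to 0.0691) and SERPINE2 of 1.13 to 1.44.

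**Figure D3:**
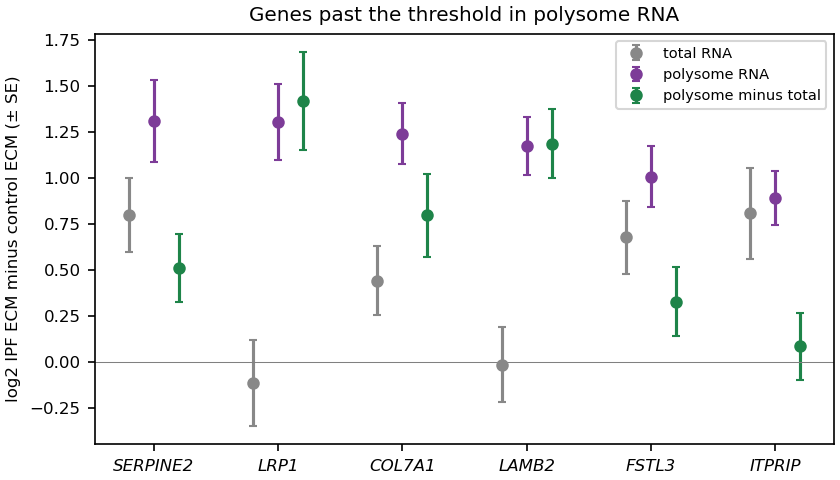
Bars show the matrix effect, IPF minus control matrix in log2 units ± SE over 10 lines, for the 6 genes that rose in polysome RNA, measured in total RNA, in polysome RNA and as their difference. LRP1 and SERPINE2 show the largest polysome values, 1.31 each.

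Collagens as a group rose in polysome RNA on IPF matrix. Of 20 measured collagens, 17 had positive effects, with a median of 0.69. COL7A1 alone passed over all genes, and 13 passed adjusted over the list alone, among them COL4A2 (1.05 ± 0.19), COL8A1 (0.98 ± 0.18) and COL18A1 (0.90 ± 0.20). The list test gave an adjusted p = 2.25e-14, and adjusted p = 0.101 with an estimated correlation. Of 38 non-collagen matrix proteins, 36 had positive effects and all 10 lines had a positive mean (median 0.42, adjusted p = 1.55e-14), with adjusted p = 0.101 with an estimated correlation. LAMB2 passed over all genes, and 14 passed adjusted over the list alone. Values were 1.5 for the proteoglycan VCAN, 1.05 for the laminin chain LAMA2 and 0.71 for the elastic fibre gene FBLN5. Targets of the microRNA miR-29, many of them collagens, were higher in 26 of 31 cases (median 0.43, adjusted p = 1.14e-12, 1 over all genes, 14 adjusted over the list alone), with adjusted p = 0.101 with an estimated correlation. Fibroblast markers overlap with these lists and rose too (13 of 15 positive, median 0.41, adjusted p = 2.42e-05, 5 adjusted over the list alone), with adjusted p = 0.129 with an estimated correlation. The mean rise of collagens was 0.54 ± 0.49 in control and 0.75 ± 0.54 in IPF fibroblasts (SD, n = 5 lines each; exact two-sided p of the difference 0.516).

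Messages for folding and cutting secreted proteins moved with them. Of 23 chaperones and folding factors of the endoplasmic reticulum, 20 had positive effects and all 10 lines had a positive mean (median 0.29, adjusted p = 6.95e-07), with adjusted p = 0.101 with an estimated correlation. None passed over all genes and 7 did adjusted over the list alone. The co-chaperone DNAJB9 had 0.82 ± 0.18, the lectin chaperone CANX 0.54 ± 0.16, and HYOU1 and PDIA4 0.61 and 0.55. Of 21 matrix proteases and inhibitors, 16 were positive (median 0.38, adjusted p = 3.91e-05), with adjusted p = 0.129 with an estimated correlation. SERPINE2 passed over all genes, and 7 rose and 1 fell adjusted over the list alone. MMP14 had 1.05, the stromelysin MMP10 had 1.43 and the inhibitor TIMP4 had −0.50, so proteases and an inhibitor of proteases were both among the higher members. In polysome against total RNA MMP14 had −0.81 in control line 1, against 2.70 to 3.66 in the other control lines. The polysome library of that line on control matrix scored with total RNA. Its matrix effect can therefore hold a fraction difference for MMP14 and other polysome-enriched genes, such as BMP1, LTBP3 and LAMB2. Their values without that line are not given here. Collagen processing enzymes were positive in 18 of 23 cases (median 0.34, adjusted p = 5.91e-04, 6 adjusted over the list alone), with adjusted p = 0.457 with an estimated correlation. Examples are the collagen chaperone FKBP10 (0.94), the procollagen protease BMP1 (0.67) and the prolyl hydroxylase P4HA3 (0.76).

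**Figure D4:**
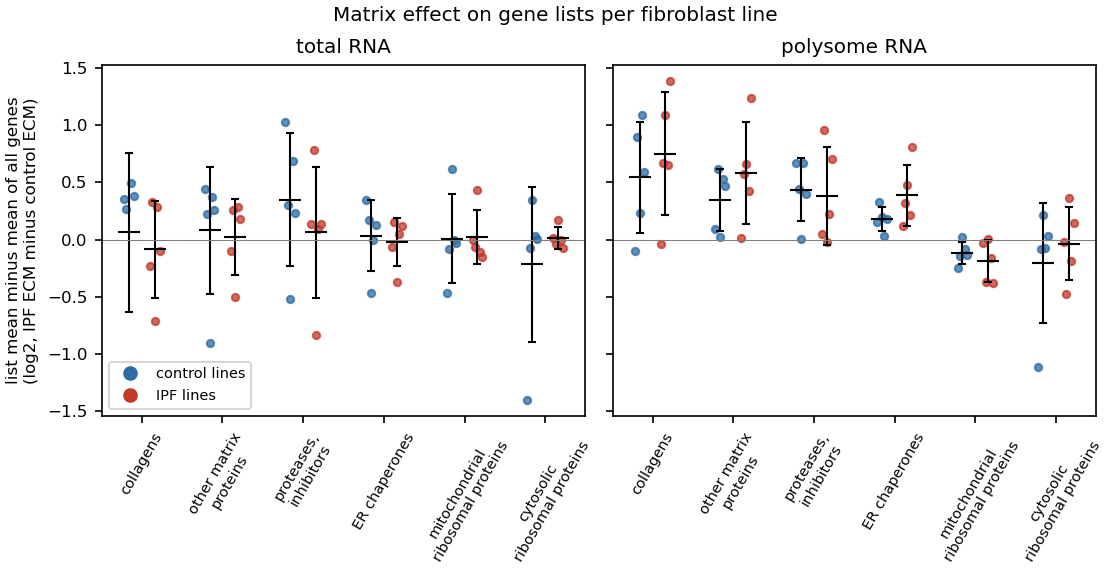
Each point is the effect of IPF matrix on the mean of a gene list minus the mean of all genes in 1 line, in log2 units. Total RNA is in the left panel and polysome RNA in the right panel, with separate bars for mean ± SD over the 5 lines of each origin. All 10 lines lie above 0 in polysome RNA for non-collagen matrix proteins and for endoplasmic reticulum chaperones.

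Signalling lists had smaller median rises, a difference in size that was not tested. YAP and TAZ targets, genes switched on by stiffness, were positive in 18 of 21 cases (median 0.17, adjusted p = 0.00512, 2 adjusted over the list alone), with adjusted p = 0.129 with an estimated correlation. The growth factor genes CCN1 and CCN2 had 0.87 ± 0.29 and 1.20 ± 0.31. TGF-beta response genes were positive in 15 of 20 cases (median 0.17, adjusted p = 0.00649, 3 adjusted over the list alone), with adjusted p = 0.299 with an estimated correlation. The oxidase NOX4 had 0.78 and LTBP3 0.72, while ID1, an inhibitor of differentiation, had −0.53. Integrins and focal adhesion genes were positive in 21 of 28 cases (median 0.19, adjusted p = 0.00171, none adjusted over the list alone), with adjusted p = 0.299 with an estimated correlation, and ITGAV and ITGA2 had 0.92 and 0.87. ATF4 and amino acid response genes were positive in 21 of 28 cases (median 0.20, adjusted p = 0.00137, 2 adjusted over the list alone), with adjusted p = 0.457 with an estimated correlation. The amino acid transporter subunits SLC3A2 and SLC7A5 had 1.10 and 0.72. Without batch 2 the median of this list was 0.05 and that of TGF-beta response genes 0.08, and neither passed. Integrins had 0.04 without control line 1 and batch 2 and did not pass. All 8 smooth muscle and pericyte markers were positive (median 0.20, adjusted p = 0.00557, none adjusted over the list alone), with adjusted p = 0.129 with an estimated correlation. They rose beside the matrix genes, with NOTCH3 at 0.51 and CSPG4 at 0.42.

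Other lists fell in polysome RNA on IPF matrix, with smaller effects and no member past the threshold over all genes. Of 74 mitochondrial ribosomal proteins, 61 were lower (median −0.14, adjusted p = 7.56e-06), with adjusted p = 0.129 with an estimated correlation, and MRPL52 had −0.57 and MRPS6 −0.51. Of 25 interferon-stimulated genes, 22 were lower (median −0.23, adjusted p = 2.1e-04, 1 adjusted over the list alone), with adjusted p = 0.129 with an estimated correlation. The immunoproteasome gene PSMB9 had −0.77 on the probe used and 0.05 on another, and the antiviral gene IFITM1 had −0.52. Glycolysis and hypoxia genes were lower in 24 of 30 cases (median −0.16, adjusted p = 1.17e-04, 2 adjusted over the list alone), with adjusted p = 0.457 with an estimated correlation. Control line 1 ran the opposite way (0.62, against −0.82 to −0.43 in the other control lines), and without it the median was −0.32. Among them, the mitophagy receptors BNIP3 and BNIP3L had −0.70 and −0.48. Cell cycle genes were lower in 33 of 44 cases (median −0.15, adjusted p = 6.07e-04), with adjusted p = 0.457 with an estimated correlation, and the replication gene GINS2 had −0.75. Without IPF line 1 the median of cell cycle genes was −0.06 and did not pass.

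Components of the translation and splicing machinery were lower as well. Cytosolic ribosomal proteins were lower in 53 of 69 cases (median −0.11, adjusted p = 8.53e-04), with adjusted p = 0.584 with an estimated correlation. Control line 1, the line with the mismatched libraries, stood at −1.12, and without that pair the median was 0.04 and the call was lost. Spliceosome genes were lower in 26 of 39 cases (median −0.15, adjusted p = 0.00659), with adjusted p = 0.261 with an estimated correlation. Oxidative phosphorylation subunits were lower in 48 of 67 (median −0.05, adjusted p = 0.025), with adjusted p = 0.523 with an estimated correlation. Control line 1 stood at −0.59, and without it the median was −0.04 (adjusted p = 0.967). Translation factors were lower in 31 of 46 (median −0.05, adjusted p = 0.0353), with adjusted p = 0.299 with an estimated correlation. In each of these last 3 lists a member with 1 of the smallest p was higher, namely the splicing factor PRPF8 (0.36), the respiratory subunit UQCRC1 (0.51) and the scaffold EIF4G1 (0.39). Control line 3 ran the opposite way in spliceosome genes (0.12) and translation factors (0.0738). Exact sign-flip tests on list means per line, chosen after the data were seen, kept 7 of the 20 lists after adjustment (0.0342 to 0.0391). These were collagens, non-collagen matrix proteins, miR-29 targets, endoplasmic reticulum chaperones, matrix proteases, YAP and TAZ targets and mitochondrial ribosomal proteins.

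The remaining lists did not pass in polysome RNA. The median effect was 0.15 for myofibroblast contractile genes (adjusted p = 0.139), −0.25 for cholesterol biosynthesis (0.0651) and −0.10 for the heat shock response (0.0888). Inflammatory cytokines and NF-kappaB targets had a median of −0.04 and a mean of 0.07 (adjusted p = 0.953, test downward), and immediate early genes −0.02 and 0.04 (0.873, test downward). It was −0.03 for proteasome subunits, 0.03 for KRAB zinc finger genes, 0.16 for messages with inhibitory upstream reading frames, 0.04 for non-coding RNAs and −0.09 for histones. Markers of other cells had medians of −0.08 (epithelial), −0.06 (endothelial), 0.04 (macrophage and leukocyte) and −0.02 (mesothelial), and erythroid markers had −0.00 with a mean of 0.05. Among the genes followed throughout, COL1A2 had 0.65 ± 0.15, COL1A1 0.39 ± 0.21, COL3A1 0.47 ± 0.30, FN1 0.41 ± 0.19, POSTN 0.33 ± 0.23 and ACTA2 0.05 ± 0.14, none past the threshold (adjusted p 0.168 to 0.938).

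The matrix effect on polysome RNA minus that on total RNA measures change in polysome RNA beyond the amount of message. In this difference 15 genes rose on IPF matrix and none fell. Mean detected probes in total RNA were lower on IPF matrix, 15217.4 against 16641.4 in control and 15318.2 against 16134.6 in IPF fibroblasts. Whether that bears on the difference was not tested. LRP1 rose by 1.42 ± 0.27 log2 units (SE, n = 10 lines, adjusted p = 0.0431) and LAMB2 by 1.19 ± 0.19 (adjusted p = 0.0256). UGGT1, the glucosyltransferase that checks glycoprotein folding, rose by 1.09 ± 0.21 (adjusted p = 0.0432), the cytokine gene TNFSF15 by 1.08 ± 0.18 (adjusted p = 0.0256) and COL6A2 by 1.07 ± 0.18 (adjusted p = 0.03). The transport adaptor MAPK8IP3 (1.07 ± 0.19), SLC71A3P (1.08 ± 0.18), SHROOM4 (0.99 ± 0.18) and ZNF549 (0.98 ± 0.18) rose as well, ZNF549 with a second probe at 0.01. At least 9 of 10 lines moved upward for each of them. Without background correction TNFSF15 had 0.46, MAPK8IP3 0.53 and UGGT1 0.55, all still past the threshold. The 3 lower genes with the smallest p were NGEF (−0.87 ± 0.18, adjusted p = 0.0603), ADSL (−0.70 ± 0.15, adjusted p = 0.0691) and ZNF670 (−0.65 ± 0.14, adjusted p = 0.0826).

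Collagens led the lists of this difference, with 19 of 20 positive and 15 past the threshold adjusted over the list alone (median 0.70, adjusted p = 2.14e-11), and adjusted p = 0.279 with an estimated correlation. COL12A1 had 1.38 and COL6A3 1.00. Non-collagen matrix proteins were positive in 33 of 38 cases, with 15 up and 1 down adjusted over the list alone (median 0.41, adjusted p = 8.97e-10). The miR-29 targets (median 0.46, adjusted p = 7.16e-11, 14 adjusted over the list alone) and fibroblast markers (median 0.45, adjusted p = 2.66e-05, 8 adjusted over the list alone) rose too. So did endoplasmic reticulum chaperones (median 0.28, adjusted p = 8.44e-05, 5 adjusted over the list alone), integrins (median 0.16, adjusted p = 0.00181, 1 adjusted over the list alone) and YAP and TAZ targets (median 0.16, adjusted p = 0.0107, 2 adjusted over the list alone). For these 6 lists adjusted p = 0.279 with an estimated correlation. Control line 3 stood apart from the other control lines with 0.74 for integrins and 0.61 for YAP and TAZ targets. Without it the medians were 0.12 and 0.0964, both still past the threshold. HYOU1 had 0.92, PDIA4 0.83, ITGA2 1.08 and ITGAV 1.05.

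Collagen processing enzymes (median 0.17, adjusted p = 0.00204, 7 adjusted over the list alone, adjusted p = 0.351 with an estimated correlation) included PLOD2 at 0.71. Matrix proteases (median 0.27, adjusted p = 0.00462, adjusted p = 0.432 with an estimated correlation) had 4 members up and 1 down adjusted over the list alone, with the protease ADAMTS1 at 0.82 and MMP13 at −0.46. KRAB zinc finger genes (median 0.08, adjusted p = 0.0149, adjusted p = 0.432 with an estimated correlation) had 1 member past the threshold over all genes and 3 adjusted over the list alone. Inflammatory genes were higher (median 0.16, adjusted p = 0.0376, none adjusted over the list alone, adjusted p = 0.279 with an estimated correlation), with the adhesion molecule VCAM1 at 0.66 (another probe −0.11) and the dismutase SOD2 at −0.33. Downward, mitochondrial ribosomal proteins were lower in 58 of 74 cases (median −0.16, adjusted p = 3.39e-05, adjusted p = 0.357 with an estimated correlation). Translation factors (median −0.10, adjusted p = 0.021, adjusted p = 0.279 with an estimated correlation) were lower with EIF2B5 at −0.47, and interferon-stimulated genes (median −0.12, adjusted p = 0.021, adjusted p = 0.283 with an estimated correlation) with IRF7 at −0.58 (another probe 0.03). Proteasome subunits were lower too (median −0.08, adjusted p = 0.0275, adjusted p = 0.467 with an estimated correlation), and none of these 4 lists had a member past the threshold over all genes or adjusted over the list alone.

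No list passed an exact test on its mean per line for this difference (lowest adjusted p = 0.0684 over 10 lines). The count of 15 genes was 14 without the 2 mismatched libraries, 29 with the authors' values, 138 with array quality weights, 0 without the pairing by line, 3 with a regression of polysome on total RNA and 0 to 26 when single lines were left out. The run without the 2 mismatched libraries held the same lines as that without control line 1, so it is not a milder exclusion. COL1A1 (0.65 ± 0.21), COL1A2 (0.75 ± 0.18), COL3A1 (0.89 ± 0.27), CCN2 (0.52 ± 0.18), FN1 (0.22 ± 0.21), POSTN (0.35 ± 0.25) and ACTA2 (−0.23 ± 0.12) did not pass (adjusted p 0.149 to 0.676).

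In total RNA, which measures message amount, no gene passed on IPF against control matrix. By limma 0 genes were past an adjusted p of 0.05 (lowest 0.106), 1050 had an unadjusted p under 0.05 where chance gives 606.55, and array quality weights gave 195. Values with the smallest p were 0.85 ± 0.18 for HMOX1, the heme oxygenase of the oxidant response, 0.94 ± 0.19 for LMCD1 and 0.79 ± 0.18 for KANK4 (SE, n = 10 lines). On the lower side they were −0.71 ± 0.11 for the muscle gene TRIM55, −0.69 ± 0.11 for the chemokine CCL7 and −0.75 ± 0.13 for SNCG. COL1A1 (−0.26 ± 0.20), COL1A2 (−0.10 ± 0.18), COL3A1 (−0.42 ± 0.27), FN1 (0.19 ± 0.18), POSTN (−0.01 ± 0.20), ACTA2 (0.28 ± 0.14) and CCN2 (0.68 ± 0.24) did not pass either.

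The matrix lists that rose on polysomes had median effects in total RNA of −0.09 for collagens (adjusted p = 0.776), 0.05 for non-collagen matrix proteins (0.555) and −0.03 for endoplasmic reticulum chaperones (0.847). In total RNA 5 lists passed, with no member past the threshold over all genes or adjusted over the list alone. ATF4 and amino acid response genes were higher in 22 of 28 cases (median 0.17, adjusted p = 0.0158), with SLC7A5 at 0.78, SLC3A2 at 0.72 and the stress sensor SESN2 at 0.51. Glycolysis and hypoxia genes were lower in 26 of 30 (median −0.18, adjusted p = 0.00522), with P4HA1 at −0.62 and BNIP3 at −0.61. Cell cycle genes were lower in 35 of 44 (median −0.14, adjusted p = 0.0196), with the spindle motor KIF11 at −0.43 and the reductase RRM2 at −0.50. Spliceosome genes were lower in 29 of 39 (median −0.07, adjusted p = 0.0196), with SNRPD3 at −0.35. For each of the 5 lists adjusted p = 0.978 with an estimated correlation. Without batch 2 the median of the ATF4 list was 0.03, and without IPF line 1 that of cell cycle genes was −0.05, neither past the threshold. Spliceosome genes had −0.03 without control line 1 and glycolysis and hypoxia genes −0.10 without IPF line 3, and these calls were lost too. Cytosolic ribosomal proteins were lower in 59 of 69 cases (median −0.10, adjusted p = 0.0197), with control line 1 at −1.40 and a mean of 0.01 in IPF lines. Without the 2 mismatched libraries that median turned to 0.03.

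Whether cells of the 2 origins respond differently to the matrix was tested as an interaction. No gene passed by limma in total RNA, polysome RNA or their difference (lowest adjusted p = 1.00, 0.982 and 1.00, with 187, 282 and 163 genes at an unadjusted p under 0.05). Within control fibroblasts, CCL7 fell in total RNA by 1.12 ± 0.15 (SE, n = 5 lines, adjusted p = 0.0413), and its interaction had an adjusted p of 1.00. This gene falls outside the rule for named genes and was chosen after its values were seen. That count of 1 was 0 without background correction, with the authors' values and without the 2 mismatched libraries, and 132 with array quality weights. In IPF fibroblasts 0 genes passed in total RNA (369 at an unadjusted p under 0.05). In polysome RNA 0 passed within control (615) or IPF fibroblasts (1028), and the difference gave 0 in both (549 and 985).

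IPF and control fibroblasts were compared over 5 lines each. No gene passed by limma in total RNA (lowest adjusted p = 0.186; 655 genes at an unadjusted p under 0.05), polysome RNA (0.757, with 511 genes) or their difference (1.00, with 291), where chance gives 606.55. In total RNA the actin nucleator FMN2 had 0.91 ± 0.14, the tendon transcription factor MKX 0.43 ± 0.08 and SERPINB7 0.76 ± 0.15 (SE, n = 10 lines). The junction gene JUP had −1.37 ± 0.23, JCHAIN −0.85 ± 0.18 and the metallothionein MT1H −0.93 ± 0.20. COL3A1 had −0.75 ± 0.25, COL1A1 −0.51 ± 0.28, CCN2 0.58 ± 0.22, POSTN 0.38 ± 0.44 and ACTA2 0.00 ± 0.19. In polysome RNA the peptide gene KISS1 had 2.44 ± 0.51, OLFML2B 1.32 ± 0.31 and the cytokine IL32 1.13 ± 0.26, and MT1F had −1.02 ± 0.21, DIRAS3 −0.75 ± 0.15 and the Wnt antagonist FRZB −0.67 ± 0.14. In the difference CAPN15 had 0.66 ± 0.15 and CELF2 −0.54 ± 0.13.

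Among the lists that differed by origin, no member passed over all genes, and only TM7SF2 and a pair of matrix proteins passed adjusted over the list alone. Cell cycle genes were lower in IPF fibroblasts in 41 of 44 cases in total RNA (median −0.32, adjusted p = 1.74e-08) and 42 of 44 in polysome RNA (median −0.30, adjusted p = 6.44e-13). These became adjusted p = 0.676 with an estimated correlation in total RNA and adjusted p = 0.902 with an estimated correlation in polysome RNA, and exact tests of the line means gave 0.333 and 0.238. ATF4 and amino acid response genes were higher in total RNA (median 0.16, adjusted p = 0.00193, adjusted p = 0.706 with an estimated correlation) and in 25 of 28 cases in polysome RNA (median 0.28, adjusted p = 4.35e-05, adjusted p = 0.902 with an estimated correlation). Interferon-stimulated genes were higher in both (medians 0.14 and 0.16, adjusted p = 0.027 and 0.0402), although RSAD2 had −0.23 in total RNA. They had adjusted p = 0.71 and 0.902 with an estimated correlation, and without IPF line 4 the medians were −0.00212 and −0.00600 and neither passed.

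In total RNA of IPF fibroblasts, collagens were lower (median −0.13, adjusted p = 0.00166), as were miR-29 targets (−0.11, adjusted p = 6.63e-04), integrins (−0.13, adjusted p = 0.00264), endoplasmic reticulum chaperones (−0.13, adjusted p = 0.03) and cholesterol biosynthesis genes (−0.29, adjusted p = 9.14e-04). For these 5 lists adjusted p = 0.676 with an estimated correlation. The sterol reductase TM7SF2 (−0.92 ± 0.24) was the 1 member of them that passed adjusted over the list alone. Collagen processing enzymes were lower too (−0.13, adjusted p = 0.0287, adjusted p = 0.71 with an estimated correlation), although the crosslinking enzyme LOX had 0.48, and without control line 1 the median turned to 0.0158 and did not pass. The medians of chaperones and cholesterol genes were −0.00751 and 0.03 without control line 1 and batch 2, and neither passed. Mesothelial markers were lower beside these groups (median −0.34, adjusted p = 0.0168, adjusted p = 0.676 with an estimated correlation). The exact test on line means gave an unadjusted p of 0.0159, and the lowest adjusted p of that test over the lists was 0.556. Of the 5 genes, UPK3B, LRRN4 and BNC1 had low mean log2 intensities (5.28, 5.13 and 5.57). The change of BNC1 was −0.17 on the probe used and −0.08, 0.03 and 0.0009 on others. Cytosolic ribosomal proteins were higher (0.15, adjusted p = 5.84e-05), as were oxidative phosphorylation subunits (0.08, adjusted p = 0.041), and both had adjusted p = 0.71 with an estimated correlation. KRAB zinc finger genes (0.08, adjusted p = 0.0123) and non-coding RNAs (0.15, adjusted p = 0.00284) were higher with adjusted p = 0.676 with an estimated correlation. Without control line 1 the medians of cytosolic ribosomal proteins and oxidative phosphorylation subunits were −0.00158 and −0.0105, and 8 rather than 14 lists passed without its 2 mismatched libraries, where non-coding RNAs had 0.0135.

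In polysome RNA, collagen processing enzymes (median 0.24, adjusted p = 0.0195), matrix proteases (0.23, adjusted p = 0.0195) and non-collagen matrix proteins (0.18, adjusted p = 0.0402) were higher in IPF fibroblasts. Without control line 1 and batch 2 the medians of the last 2 turned to −0.0652 and −0.0139, and that of the first was 0.0472. The glycoprotein FBLN1 had 1.71 ± 0.45 and was among 2 matrix proteins past the threshold adjusted over the list alone, while TNC had −0.85 and MMP3 had −0.75. Mitochondrial ribosomal proteins (−0.09, adjusted p = 0.0455), oxidative phosphorylation subunits (−0.10, adjusted p = 0.0402), macrophage and leukocyte markers (−0.08, adjusted p = 0.0457) and contractile genes (median −0.02, mean −0.14, adjusted p = 0.0402) were lower. Contractile genes turned to 0.0315 without control line 5, which stood apart, and to 0.0468 without IPF line 5, and did not pass in either run. For these 7 lists adjusted p = 0.902 with an estimated correlation. For the origin of the cells, no exact test on list means passed after adjustment.

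In polysome RNA minus total RNA, 11 lists differed by origin, all with adjusted p = 0.779 with an estimated correlation. Collagens (median 0.27, adjusted p = 0.0103), non-collagen matrix proteins (0.26, adjusted p = 4.09e-04), collagen processing enzymes (0.30, adjusted p = 4.09e-04), matrix proteases (0.26, adjusted p = 0.0155) and fibroblast markers (0.24, adjusted p = 0.0399) were higher in IPF fibroblasts. Cytosolic ribosomal proteins were lower in 68 of 69 cases (median −0.20, adjusted p = 2.06e-06). Mitochondrial ribosomal proteins (−0.11, adjusted p = 3.82e-04), oxidative phosphorylation subunits (−0.15, adjusted p = 1.34e-04), KRAB zinc finger genes (−0.08, adjusted p = 0.0461), non-coding RNAs (−0.16, adjusted p = 0.00594) and histones (−0.16, adjusted p = 0.00114) were lower. Without the 2 mismatched libraries of control line 1, 1 list passed, the median of cytosolic ribosomal proteins turned to 0.07, and those of matrix proteases and non-coding RNAs were 0.0153 and −0.0145. Without control line 1 and batch 2, collagens had 0.00426, collagen processing enzymes 0.0118, non-collagen matrix proteins −1.52e-05 and fibroblast markers −0.00864. Over at most 20 alternatives, single lists by origin kept their call in 8 to 18 in total RNA, 6 to 18 in polysome RNA and 10 to 17 in the difference.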

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

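The tests of control line 1, of the matrix messages, of the sets of batches and of regrouped lines for the origin of the cells were chosen only after the result was seen. The other regroupings of samples given in this section were fixed before the data were examined. Each value was compared with the other 4 lines of its group, and 53 of 380 groups held a line that stood apart from the rest. Chance gives about 1 in 20 groups. A separate check looked for genes and lists in which all control lines moved one way and all IPF lines the other, and found 0.

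Many of these values come from control line 1 in polysome against total RNA (log2 units). On the side enriched in the other control lines this line had −0.81 for MMP14, −0.60 for LAMB2, −0.50 for CHPF, −0.48 for P3H3, −0.35 for ISLR, −0.17 for the protease PLAU, −0.16 for BMP1, −0.11 for P4HB and −0.10 for the collagen receptor DDR1. It had 0.0775 for SPON2, 0.11 for CEBPB, 0.14 for GPC1, 0.14 for the sterol cyclase LSS and 0.19 for the glycolytic enzyme TPI1. On the side depleted in them it had 0.53 for RPL26, 0.29 for RPL21, −0.0913 for ATP5F1E, −0.15 for ATP5ME, −0.20 for EIF3H, −0.31 for SAT1 and −0.0183 for ZNF615. Gene lists of this line stood apart as well. Its matrix effect for cytosolic ribosomal proteins was −1.40 in total RNA and −1.12 in polysome RNA. In polysome RNA its matrix effect was −0.59 for oxidative phosphorylation subunits and 0.62 for glycolysis and hypoxia genes, and in the difference it was 0.0864 for translation factors. Its level relative to all genes was 4.55 for cytosolic ribosomal proteins in total RNA. In polysome minus total RNA its levels were 0.11 for cytosolic ribosomal proteins, −0.21 for collagen processing enzymes, −0.22 for matrix proteases and −0.12 for non-coding RNAs.

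In control line 1, 2 libraries scored inside the range of the other fraction, those labelled polysome RNA on control matrix and total RNA on IPF matrix. Poor separation of polysomes cannot be decided by the library labelled total RNA. Its score of 1.16 is part of the observation that raised the question and comes from the culture on IPF matrix. The polysome library out of place comes from the culture on control matrix. A matrix effect on total RNA is argued against by the other control lines, whose score moved by −0.0646 (SD 0.195, n = 4 lines). An exchange of labels between them stays open, since the 2 libraries out of place are the observation that raised it and no separate test was made. Neither library was moved to another group.

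Other lines stood apart in single genes. In polysome RNA the matrix effect was −0.52 for FN1 in IPF line 1, 2.81 for POSTN in IPF line 5 and 2.79 for SERPINE2 in control line 4. In the difference of the fractions it was 0.32 for MAPK8IP3 in IPF line 3, and 1.83 for SHROOM4 and 2.04 for ZNF549 in control line 3. Polysome against total RNA gave 2.71 for GPC1 and −2.78 for RPL23 in IPF line 4 and 1.79 for LTBP3 in IPF line 5. These genes were named by the rule, except for the values of single lines, which were chosen after they were seen.

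Other lines also stood apart in lists and depth. Control line 3 had matrix effects in polysome RNA of 0.0738 for translation factors and 0.12 for spliceosome genes, and in the difference of 0.74 for integrins and 0.61 for YAP and TAZ targets. IPF line 4 had 0.18 for interferon-stimulated genes in the difference. Levels relative to all genes in total RNA were 1.95 for collagens and 1.11 for miR-29 targets in IPF line 2 and 1.57 for cell cycle genes in IPF line 5. In polysome RNA they were 4.18 for contractile genes in control line 5 and 0.60 for interferon-stimulated genes in IPF line 4. In the difference cytosolic ribosomal proteins stood at −1.38 in IPF line 4. Detected probes numbered 17369 in total RNA of control line 3 on control matrix and 12707 in polysome RNA of IPF line 5 on control matrix.

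The counts of genes were set against regrouped samples. For the matrix effect in polysome RNA, the real grouping was the only 1 of 100 to reach its 6 genes, and the highest other count was 0. For polysome minus total RNA it was the only 1 of 100 to reach 15 genes (highest other 0), and for polysome against total RNA the only 1 of 100 to reach 6081 (highest other 3893). In total RNA the matrix count of 0 was reached by all 100, and so were the interaction counts of 0 (highest others 0 in total RNA, 0 in polysome RNA and 29 in their difference). Within 1 origin only 16 groupings exist, too few for a share under 0.05. There, all 16 reached the counts of 0, and 2 of 16 reached the count of 1 in total RNA of control fibroblasts (highest other 1).

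For the origin of the cells all 100 regroupings reached the real count of 0, and others gave up to 1326 genes in total RNA, 31 in polysome RNA and 1407 in their difference. The grouping of batches 1, 2 and 5 against 3, 4 and 6 was chosen after the lines were seen to part that way. It gave 2619 genes in total RNA, 880 in polysome RNA and 6 in their difference, and these counts restate what was seen and are no test of it. A difference between batches is consistent with the control and IPF lines of a batch deviating together in total RNA (mean r 0.402 over 4 pairs, against −0.132 for other pairs). The exact one-sided p was 0.0833 over 24 pairings, so batches and differences between lines cannot be told apart here, because only 4 batches hold lines of both origins.

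Messages for collagens and other matrix proteins were higher in polysome RNA on IPF matrix, by 0.526 log2 units on average over 58 genes (SD 0.404, n = 10 lines). Purer polysome fractions on IPF matrix are argued against by a shift of 0.497 that remained after each line's slope on the fraction difference was removed (exact p = 0.0117). A rise carried by the mismatched libraries and batch 2 is argued against by an exact p of 0.03125 over the other 7 lines. A general rise of messages translated at the endoplasmic reticulum may be part of it, since lysosomal and surface receptor messages shifted by 0.333 (exact p = 0.00391 over 10 lines). Whether it is the whole cannot be told apart, since the difference from those messages, 0.193 (SD 0.382, n = 10 lines), had an exact p of 0.139 and the spread between lines keeps it open.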

How the results depend on the processing

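The runs without the 2 mismatched libraries, without batch 2, and without control line 1 and batch 2 together were chosen only after the result was seen. So were the covariate for sets of batches, the exact tests on list means and the sign flips with array quality weights. The others were chosen before the data were examined. Of 66 named genes past the threshold in polysome against total RNA, 64 stayed past it under every alternative, against 0 of 6 in the matrix effect on polysome RNA and 0 of 9 in polysome minus total RNA. All of these genes kept their direction. Array signal over background limits the genes that can be tested, 5602 with detection on all 40 arrays against 19951 with no filter. Where no other reason is given, the cause was not tested.

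With an estimated correlation 0 lists passed in any comparison, where 5, 20 and 15 had passed for the matrix effect (total RNA, polysome RNA, difference), 14, 10 and 11 for the origin and 13 in polysome against total RNA. Exact tests gave 0, 7 (6 up, 1 down) and 0 for the matrix effect, 0, 0 and 0 for the origin and 31 (20 up, 11 down) in polysome against total RNA.

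Array quality weights gave 195 genes for the matrix effect in total RNA (83 up, 112 down; 0 with equal weights), 220 in polysome RNA (165 up, 55 down; 6) and 138 in the difference (120 up, 18 down; 15). Over 20 sign flips of lines with such weights the highest other counts were 72, 4 and 0. These flips were chosen after the data were seen, and 20 are too few for a share under 0.05. Within control fibroblasts they gave 132 in total RNA (57 up, 75 down), 23 in polysome RNA (17 up, 6 down) and 1 in the difference, and within IPF fibroblasts 43 in the difference, all up.

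Without the replicate block, that is without pairing by line, the matrix effect gave 1 gene in polysome RNA and 0 in the difference. The block changed the call of no other count. Separate fits of the origins gave 0 in total RNA of control fibroblasts, and a regression of polysome on total RNA gave 3 in the difference.

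Without background correction the counts were 1 in total RNA (down), 0 in control fibroblasts and 25 in the difference. The authors' values gave 0 in total RNA and 1 in polysome RNA of control fibroblasts, and 29 in the difference (28 up, 1 down). No detection filter, with more genes tested, gave 2 in polysome RNA, 5 in the difference and 2 lists (1 up, 1 down) for the origin in polysome RNA. Detection on all 40 arrays, with fewer genes tested, gave 0 and 1 in total and polysome RNA of control fibroblasts, and 3830 genes (2281 up, 1549 down) and 8 lists (3 up, 5 down) in polysome against total RNA. All probes gave 0 in total RNA of control fibroblasts, 3 in polysome RNA, 50 in the difference (49 up, 1 down) and 9211 in polysome against total RNA (4623 up, 4588 down).

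Without the 2 mismatched libraries the matrix effect gave 2 genes in total RNA (both down), 13 in polysome RNA (10 up, 3 down), and 0 and 1 in total and polysome RNA of control fibroblasts. These fits held the same lines as those without control line 1. They differed only in the mean intensities used for the variance trend, so the 2 runs are not separate checks. Where their counts differ, calls near the threshold are unstable. Without the 2 libraries, lists for the origin numbered 8 (2 up, 6 down), 6 (2 up, 4 down) and 1 (down) in total RNA, polysome RNA and the difference. Without batch 2 there were 0 in total RNA of control fibroblasts, 3 in polysome RNA, 6 in the difference and 6 lists (3 up, 3 down) for the origin in polysome RNA. Without control line 1 and batch 2 there were 0 and 1 in total and polysome RNA of control fibroblasts, 10 in polysome RNA and 70 in the difference (69 up, 1 down). Lists then numbered 12 (6 up, 6 down) for the matrix effect in total RNA, 7 (2 up, 5 down) and 2 (both down) for the origin in total RNA and the difference, and 20 (10 up, 10 down) in polysome against total RNA.

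Leaving out single lines gave 0 to 9 genes for the matrix effect in total RNA (9 without control line 1) and 0 to 0 in control fibroblasts. In polysome RNA it gave 0 to 13, with 13 without control line 1, 1 without control line 3, 3 without IPF line 4 and 0 without control line 2, 4 or 5 or IPF line 2 or 3, and 0 to 1 in control fibroblasts. In the difference it gave 0 to 26, with 26 without IPF line 5, 9 without IPF line 1, 5 without control line 1, 2 without IPF line 3 and 0 without control line 2, 3, 4 or 5 or IPF line 2 or 4. For the origin it gave 0 to 1 in total RNA (1 without control line 3) and 0 to 8 in polysome RNA (8 without control line 4), and for polysome against total RNA 5538 to 6578. Lists ranged from 2 to 9, 18 to 24 and 9 to 17 for the matrix effect, 8 to 17, 5 to 15 and 1 to 16 for the origin and 11 to 15 in polysome against total RNA. The share of the matrix in the spread ranged from 6.03% to 7.05% in total and 5.76% to 7.28% in polysome RNA, and that of the origin from 4.79% to 7.28% and 3.99% to 6.09%. With a line left out fewer arrays remain, so the equal share lies above 5.26%. These shares are therefore not directly comparable with those of all lines.

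Lists that turned direction held no call there, except for 1. For cytosolic ribosomal proteins the matrix effect in total RNA was −0.173 to 0.0284 with single lines left out, with 0.0284 without control line 1 and without the 2 mismatched libraries, and 0.0354 without control line 1 and batch 2 (adjusted p = 0.0215). For the origin it was −0.00158 to 0.211 in total RNA and −0.271 to 0.0678 in the difference, with −0.00158 and 0.0678 without control line 1 and 0.0678 without the mismatched libraries. By origin in the difference, matrix proteases had 0.0153 to 0.364 and non-coding RNAs −0.280 to −0.0145, with 0.0153 and −0.0145 without control line 1 or the mismatched libraries and −0.00947 and 0.00669 without control line 1 and batch 2. Interferon-stimulated genes by origin had −0.00212 to 0.264 in total RNA and −0.00600 to 0.261 in polysome RNA, the lowest without IPF line 4. Without control line 1 and batch 2, oxidative phosphorylation subunits had −0.0228 for the matrix effect in polysome RNA and −0.00946 by origin in total RNA. By origin in polysome RNA, non-collagen matrix proteins then had −0.0139 and matrix proteases −0.0652. In the difference by origin, collagens had 0.00426, non-collagen matrix proteins −1.52e-05 and fibroblast markers −0.00864. For some of these values the median kept its sign and the direction of the test turned. In other lists the median turned while the test kept its direction. Among them were collagen processing enzymes by origin in total RNA (0.0158 without control line 1), contractile genes by origin in polysome RNA (0.0468 without IPF line 5) and histones in polysome against total RNA (0.0628 with detection on all 40 arrays).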

Other observations

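The tests of lysosomal, surface receptor and cytosolic enzyme messages, and of whether polysome RNA responds alike in both origins, were chosen only after the result was seen. The comparison of matrix and origin in polysome RNA, and that of total RNA in both origins, were written before the data were examined.

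Messages for other proteins made at the endoplasmic reticulum also rose in polysome RNA on IPF matrix. The 29 lysosomal enzymes and membrane proteins had a mean shift of 0.37 log2 units (SD 0.29, n = 10 lines, 9 higher; exact two-sided p = 0.00391). The 38 surface receptors and MHC class I chains had 0.30 (SD 0.22, n = 10 lines, all higher; exact p = 0.00195). In total RNA the same lists had 0.10 (exact p = 0.555) and −0.01 (exact p = 0.979), and 43 cytosolic metabolic and structural enzymes had −0.08 in polysome RNA (exact p = 0.184). These lists were chosen after the data were seen.

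IPF matrix may move polysome RNA toward that of IPF fibroblasts. The test was the correlation across genes between matrix effect and difference of origins, which was 0.265, and genes are not independent replicates. It was reached by 29 of 252 regroupings of lines, 11.5% (highest other 0.454), so the threshold set before the data were examined was missed. The sign of r cannot decide the question. The mismatched polysome library, from control fibroblasts on control matrix, scored with total RNA. This library enters the matrix effect and the difference of origins with the same sign, so it can raise r by itself. A value of r without it is not given here. The effect stays open because a threshold missed with 10 lines does not exclude it.

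The matrix may act alike in fibroblasts of both origins. Across genes, the mean matrix effects in control and in IPF fibroblasts correlated with r = 0.375 in total RNA, reached by 6 of 1024 sign flips of lines (0.586%; highest other 0.414). In polysome RNA r was 0.355, reached by 100 of 1024 (9.77%, highest other 0.514), which leaves it open there. Mean detected probes in total RNA were lower on IPF matrix in control (15217.4 against 16641.4) and IPF fibroblasts (15318.2 against 16134.6), though not in every line. Whether this shift, shared by both origins, contributes to r in total RNA was not tested. The mismatched libraries of control line 1 were kept for these correlations.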
